A study of Mus musculus with 10 samples.

How the data were processed

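RNA from CD4+CD25+ T cells of the lymph nodes of mice aged 17 to 19 days was measured on 10 Affymetrix arrays: 4 from wild type mice (WT), 3 from heterozygous (he) and 3 from homozygous (me) SHP-1 knockout mice. Per the labels, the cells were harvested with an isolation kit and not cultured, RNA was amplified from 20 ng, and 10 ug of the amplified RNA was labelled with biotin. The deposited values are intensity on a linear scale, 1 per probe set and array. The authors' summarisation, background correction and scaling are not given in the sources used here. Array medians of the deposited intensity ran from 148 to 188, and the sorted values differed between arrays.

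Of 45101 probe sets, 64 controls were left out and 45037 were tested. The array annotation named 1 gene for 34945 probe sets, several for 932 and none for 9160. Values were transformed as log2(intensity + 32) and, because array medians differed by over 0.1 on the log2 scale, quantile normalised between arrays. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes. The number of arrays limits the precision of every comparison.

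The comparisons were me against WT, he against WT and me against he, with a moderated F test over the 3 genotypes. Each used limma 3.58.1 in R 4.3.3 on all 10 arrays (lmFit and eBayes with the default prior, 7 residual degrees of freedom), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Differences are log2 with the standard error of the fit, and group values are means with the standard deviation over arrays. Ptpn6 was also compared by 2-sided exact permutation of arrays. The 34 gene lists, 11 of them markers of other cell types, were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Of 922 list entries 822 were matched to a measured gene, 10 of them through a synonym. The covariance of the 2 differences that share WT was set beside 100 simulations, and genes near Ptpn6, 100 on either side, were compared with all others by Fisher's exact test.

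These comparisons, tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. The rule names Ptpn6. It names up to 12 genes in each direction among called probe sets at or above the median level whose groups do not overlap, or the 5 with the smallest p where fewer than 5 pass. It also names up to 4 members of each list with the smallest p, and Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18 and Cd4.

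After the data were examined the arrays were found to form 2 sets by correlation, and fits with array set as a block, with set and sex, with the first principal component, and within sets were added. Gene lists were also tested with a Gapdh 3' to 5' ratio or the cre hybridisation control as a covariate, without members that a marker list holds, and with fry in the blocked fit. The other settings were a replicate block, fits on 2 groups alone, a filter on low values, pseudocounts of 1 and 128, no normalisation, centring on the array median, an intensity trend with a robust prior, array weights, thresholds of 0.1 and 0.01, and leaving out each array in turn. For gene lists the mean of all probe sets of each gene was a further planned setting. Every other split of the arrays into groups of the same sizes was fitted in the same way, with 100 drawn regroupings for the F test.

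The procedure was tested on simulated data that kept each probe set's shift between array sets and its spread within sets, with noise drawn independently for each probe set. Without a block it recovered 5 of 67 probe sets changed by 0.5 log2 units, 19 of 67 changed by 1 and 55 of 66 changed by 2, with 0 false calls. With array set as a block it recovered 26 of 67, 55 of 67 and 66 of 66, with 6 false calls. A list shifted by 0.3 was called in both fits and 0 of the 33 other lists were. With independent noise the members of a list were not correlated, so this gives no false call rate for lists in the real arrays.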

Results

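CD4+CD25+ T cells, the fraction that holds regulatory T cells (Treg cells), came from the lymph nodes of young BALB/c mice. The mice were wild type (WT, 4 arrays), heterozygous (he, 3 arrays) or homozygous (me, 3 arrays) for loss of SHP-1, the tyrosine phosphatase encoded by Ptpn6. Homozygous loss gives the motheaten phenotype, an inflammatory disease with an excess of myeloid cells. The comparisons ask which transcripts differ in these cells when 1 or both copies of Ptpn6 are lost. The labels call the arrays biological replicates and state nothing more about separate animals.

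Ptpn6 transcripts were lower in he than in WT and lower again in me. At the dimmer of its 2 probe sets the log2 values were 9.22, 9.08, 9.62 and 9.13 in WT, 8.75, 8.71 and 8.98 in he, and 8.05, 8.31 and 8.17 in me. At the brighter probe set they were 9.55, 9.63, 9.83 and 9.81 in WT, 9.30, 9.33 and 9.54 in he, and 8.84, 9.08 and 9.05 in me. No array of one genotype overlapped another genotype at either probe set. The me minus WT difference was -1.09 ± 0.14 (log2, SE), a 2.12-fold lower level, at the dimmer probe set and -0.72 ± 0.10, a 1.64-fold lower level, at the brighter one. The he minus WT differences were -0.45 and -0.32, and the me minus he differences were -0.64 and -0.40. In 2-sided exact permutation tests p was 0.0571 for me or he against WT and 0.1 for me against he at each probe set, the smallest values these group sizes allow. With limma neither probe set passed over all 45037 probe sets tested. For me against WT the adjusted p over the 2 Ptpn6 probe sets alone was 5.78e-05 at the dimmer and 7.05e-05 at the brighter one.

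**Figure D1:**
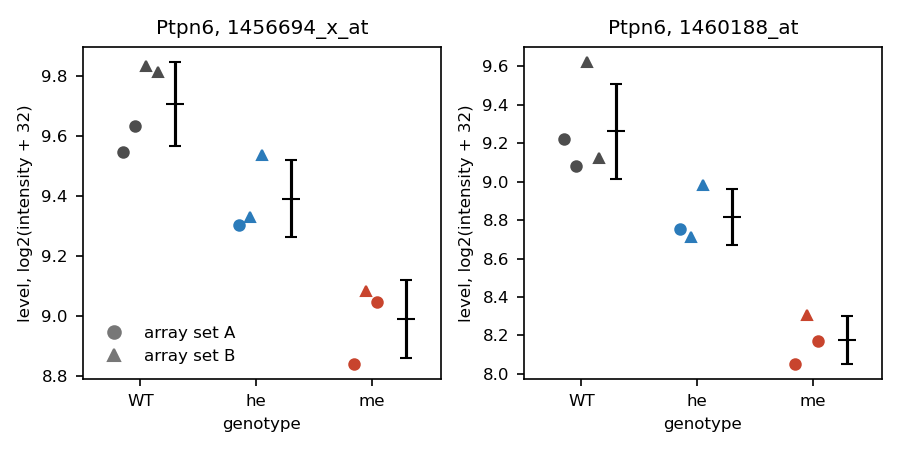
Log2 normalised intensity of the 2 Ptpn6 probe sets on each of the 10 arrays, by genotype (WT, he, me). Points are single arrays, marked by array set, and the bars beside them are group means with SD; at the dimmer probe set the means are 9.26 in WT, 8.82 in he and 8.18 in me.

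The largest differences between arrays did not follow genotype. The arrays fell into 2 sets, called A (WT 1, WT 2, he 1, me 1, me 3) and B (WT 3, WT 4, he 2, he 3, me 2). Pearson correlation across probe sets, which are not independent replicates, was 0.970 to 0.996 within sets and 0.854 to 0.944 between them. The first principal component held 82.04% of the variance and parted the sets. The array me 3 lay nearer to set B than the rest of set A did. Its score was -25.3, against -56.8 to -54.2 in the rest of set A. Its mean correlation with set B was 0.929, against 0.880 to 0.882. A block of 2 sets counts me 3 fully in set A and does not take out this difference. Between sets, 11947 probe sets were higher and 17441 were lower in B in limma. The sets were made from these same values, so neither these counts nor the first component tests them. Each genotype had arrays in both sets, so each comparison is also given with array set as a block, a choice made after seeing the data, and within each set. Xist and Eif2s3y marked WT 2, WT 4, me 1 and me 2 as male and the other arrays, with all of he, as female.

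**Figure D2:**
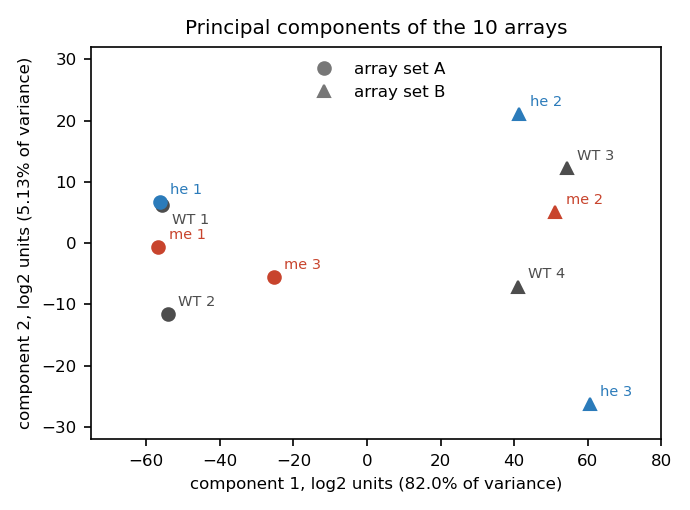
Scores of the 10 arrays on the first and second principal components of the log2 normalised intensities, which hold 82.04% and 5.13% of the variance. Each point is an array, labelled by genotype and replicate. The arrays of set A lie below 0 and those of set B above 0 on the first component. The array me 3 lies nearest to 0, at -25.3.

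In me cells, transcripts of immunoglobulin heavy chain and its partner were higher than in WT, and several receptor and signalling transcripts were lower. Jchain, the joining chain of polymeric antibodies, had a log2 value of 9.31 ± 1.18 (SD) in me (n = 3) and 7.08 ± 0.04 in WT (n = 4), a difference of 2.23 ± 0.43 (SE). Ighm, the heavy chain of IgM, differed by 1.60 ± 0.38 at its brighter probe set. Bhlhe40, a transcription factor of activated T cells, differed by 0.69 ± 0.12, Hmgn3, a nucleosome-binding protein, by 0.65 ± 0.13, and Ttn, the giant muscle protein titin, by 0.47 ± 0.09. Il17rb, a subunit of the interleukin 25 receptor, was lower in me by a log2 difference of -1.13 ± 0.18. Stab2, a scavenger receptor, differed by -0.75 ± 0.16, Hes1, a transcription factor downstream of Notch, by -0.36 ± 0.07, and Ran, the GTPase of nuclear transport, by -0.34 ± 0.07. The me and WT arrays did not overlap for any of these genes, but the naming rule asks for this when it picks genes by p. Without overlap a difference has the same sign within both array sets by construction, so neither is further support. Jchain differed by 2.90 in set A and 0.89 in set B, Ighm by 1.86 and 0.84, and Il17rb by -1.31 and -0.95.

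None of these differences passed over all genes: limma called 0 probe sets between me and WT, with 280 at an unadjusted p under 0.05 where chance gives about 2252. Without me 2 it called 2, with Jchain at an adjusted p of 0.000125 (range over the 10 left-out arrays 0.000125 to 1). Groups did not overlap at 738 probe sets (1.64%), where chance gives 5.71%. These chance values, like those of the other comparisons, take the arrays as free of sets. Each genotype spans both array sets, and with array set as a block 1934 probe sets had an unadjusted p under 0.05. The low counts with no block are therefore not read as a lack of difference.

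Transcripts of Socs2 and Tesc fell in me in the fit with array set as a block. Socs2, a suppressor of cytokine signalling, differed by -0.81 ± 0.06 (log2, SE) at its dimmer probe set (adjusted p = 0.0164) and by -0.89 ± 0.08 at the brighter one (adjusted p = 0.0249). Tesc, which encodes the calcium-binding protein tescalcin, differed by -0.67 ± 0.05 (adjusted p = 0.0164). Within sets A and B the differences were -0.75 and -0.91, -0.93 and -0.84, and -0.70 and -0.61, and every me array was lower than the WT mean of its own set. In the other settings run for these genes, none with the block, the adjusted p was 0.299 to 1. With me 3 counted in set B in the block, or with sex as a further block, no probe set passed. Socs2 was named as a member of the Treg signature list, and Tesc was chosen after its values were seen. In he the blocked differences from WT were -0.16 ± 0.06 for Socs2 at its dimmer probe set and -0.19 ± 0.05 for Tesc, and neither passed. Ptpn6 had a blocked adjusted p of 0.0559 at its brighter and 0.0900 at its dimmer probe set. These 3 probe sets were the only ones called of 45037, with 1934 at an unadjusted p under 0.05. The count was 0 without WT 2, WT 3, he 1, me 1 or me 3, 1 without WT 1 (Socs2) or WT 4 (Hmgn3), 2 without me 2 (Jchain among them) and 5 without he 2, where Gimap7 and Ptpn6 joined Socs2 and Tesc; Gimap7 was chosen after its values were seen.

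**Figure D3:**
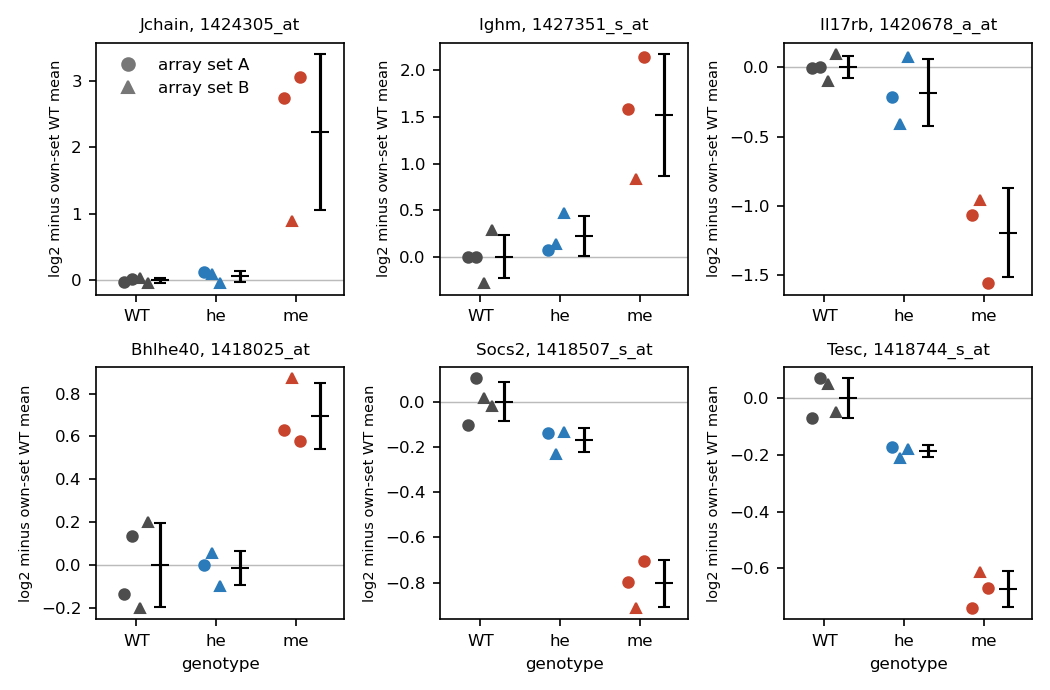
Log2 normalised intensity minus the WT mean of the same array set for 6 genes that the report names in the comparison of me with WT, on each of the 10 arrays. Points are single arrays by genotype, marked by array set, and bars are group means with SD; Socs2 differs by -0.75 in set A and -0.91 in set B.

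No gene that defines Treg cells passed between me and WT. Foxp3, the lineage transcription factor, had a log2 value of 11.14 ± 0.45 (SD) in me and 11.03 ± 0.38 in WT, a difference of 0.11 ± 0.28 (SE). The difference was -0.23 ± 0.12 for Il2ra, the CD25 chain of the interleukin 2 receptor, 0.68 ± 0.35 for Ctla4, an inhibitory receptor, 0.18 ± 0.11 for Ikzf2 (Helios), 0.01 ± 0.07 for Tnfrsf18 (GITR) and 0.13 ± 0.11 for Cd4. Without me 1 the Ctla4 difference was 0.37 and without me 2 it was 0.86. Leaving out 1 array also gave -0.14 for Il2ra (without WT 3), 0.10 for Ikzf2 (without me 1), and 0.08 and 0.21 for Cd4 (without WT 1 and me 1). With array set as a block Ctla4 differed by 0.58 ± 0.25 (unadjusted p = 0.0497, adjusted p = 0.989), and 3 of 3 me arrays were higher than the WT mean of their own set. Foxp3 was -0.04 without WT 1 and -0.12 without me 2, and Tnfrsf18 was -0.01 without WT 4, -0.06 without me 1 and -0.0055 with array set as a block. The Treg signature list, with 17 of 28 measured members higher, did not pass (adjusted p = 0.0903). With the mean of all probe sets of each gene, a planned setting, it was among the 18 lists that passed.

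Of 34 gene lists tested by camera with a preset correlation, 16 passed between me and WT, 14 upward and 2 downward. With an estimated correlation 0 passed. The fry test called 0 with no block and 1 with array set as a block. With all arrays, no list member passed over all genes in the fit with no block, and only Socs2 did with array set as a block. Members are therefore given as values. Without me 1 or without me 2 the count was 10.

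Some quality measures of the arrays also parted me from WT and he. The ratio of 3' to 5' Gapdh control probe sets was 10.88 in me 1, 9.92 in me 2 and 13.83 in me 3, against 7.84 to 9.71 in WT and he. In 2-sided exact permutation tests p was 0.0571 for me against WT and 0.1 for me against he, the smallest values these group sizes allow. The same ratio for actin did not part the genotypes, with means of 12.85 in me, 15.01 in WT and 14.97 in he (exact permutation p = 0.343 for me against WT). The intensity of the cre hybridisation control was 21736 in me 1, 10770 in me 2 and 13192 in me 3, lower in each than in every WT and he array of its own set (exact permutation p = 0.286 for me against WT over both sets). The bioB and bioD controls were also lower in 3 of 3 me arrays in this way. Each measure was then used as a covariate, a choice made after seeing the data. With the Gapdh ratio 9 lists passed between me and WT, 6 of them among the 16, and with the cre control 3 passed, all among the 16. With array set as a block as well, 9 passed with the Gapdh ratio, 8 of them among the 16. The block and the cre control let 5 pass, 4 of them among the 16, and one of these 4, cell cycle G2/M, then passed downward (adjusted p = 0.00418). At an equal residual spread, the SE of the me minus WT difference was 1.49 times as wide with the Gapdh ratio as without it and 1.56 times with the block as well. With the cre control, which differed more between array sets than between genotypes, it was 1.10 times as wide, and 1.75 times with the block.

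Several lists that passed in both the fit with no block and the blocked one did not pass with the cre control. The heat shock mean went from -0.12 (log2) to -0.05 (adjusted p = 0.354), and with the block from -0.15 to -0.13 (0.0590). The neutrophil mean went from 0.11 to 0.10 (0.219), and with the block from 0.11 to 0.04 (0.254). For macrophage and monocyte markers it went from 0.07 to -0.07 (0.959), and with the block from 0.12 to 0.03 (0.315), and for B cell and MHC class II markers from 0.14 to 0.01 (0.991), and with the block from 0.18 to -0.02 (0.880). In these 2 B cell fits with the cre control the test pointed opposite to the mean. The SD over the members of these 4 lists was 0.13 to 0.38 without a covariate and 0.12 to 0.58 with the cre control. The interferon mean went from 0.21 to 0.12 (0.773), and with the block from 0.23 to -0.04 (0.979). With the Gapdh ratio the heat shock, neutrophil and interferon lists passed with and without the block, and the macrophage and B cell lists passed without the block and not with it (0.0541 and 0.169).

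Genes of heat shock and dissociation stress fell in me: 22 of 26 were lower, with a median of -0.12 (log2; adjusted p = 2.24e-08), or adjusted p = 0.0528 with an estimated correlation. Hspa1a, the inducible Hsp70 chaperone, differed by -0.41 ± 0.10, Hspa8, its constitutive relative, by -0.23 ± 0.11, and Fos, an immediate early gene, by -0.26 ± 0.12. Without me 1 the Hspa8 difference was -0.15. The list held with array set as a block (adjusted p = 1.88e-05), with means of -0.12 in set A and -0.19 in set B.

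Markers of myeloid cells and of cells of the antibody lineage rose. Neutrophil markers were higher for 17 of 21 members (adjusted p = 2.81e-06), or adjusted p = 0.0657 with an estimated correlation. S100a8 and S100a9, the calprotectin subunits, differed by 0.56 ± 0.14 and 0.42 ± 0.12. Macrophage and monocyte markers were higher for 22 of 30 (adjusted p = 0.00684), or adjusted p = 0.0908 with an estimated correlation, with Ly86 (MD-1) at 0.42 ± 0.14. B cell and MHC class II markers were higher for 16 of 27 (adjusted p = 4.88e-05), or adjusted p = 0.0908 with an estimated correlation. Ms4a1 (CD20) differed by 0.46 ± 0.18, while Blk, a Src-family kinase that is also on the gamma delta T cell list, differed by -0.57 ± 0.23. Plasma cell markers were higher for 12 of 16 (adjusted p = 0.000314), or adjusted p = 0.0946 with an estimated correlation. Adjusted over the list alone, 2 plasma cell members passed, Jchain and Iglv1, a lambda light chain segment, which differed by 0.36 ± 0.08. Mzb1, a chaperone of antibody-secreting cells, differed by 0.28 ± 0.10 (0.18 without me 3) and did not pass. CD8 and NK cell markers were higher for 14 of 25 (adjusted p = 0.0163), or adjusted p = 0.0946 with an estimated correlation, with Cst7 (cystatin F) at 0.54 ± 0.12 and Eomes, a transcription factor of cytotoxic cells, at 0.36 ± 0.10. With no block, leaving out 1 array ended the macrophage call without WT 1 (adjusted p = 0.105), WT 2 (0.0808) or me 2 (0.370) and the B cell call without me 2 (0.0594). The CD8 and NK cell call was lost without WT 1 (0.0559), WT 2 (0.105), WT 4 (0.0552), me 1 (0.322) or me 2 (0.134). With the planned filter on low values and no block, the neutrophil, macrophage and CD8 and NK cell lists were not among the 12 lists that passed. The B cell and plasma cell lists were. In the blocked fit the neutrophil, macrophage and B cell lists held (adjusted p = 0.000337, 0.00154 and 0.000108), and the plasma cell list (0.0666) and the CD8 and NK cell list (0.0844) did not. Mean differences in sets A and B were 0.07 and 0.16 for neutrophil, 0.08 and 0.16 for macrophage, 0.22 and 0.11 for B cell and 0.27 and 0.02 for plasma cell markers.

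Markers of gamma delta T cells and innate lymphoid cells fell: 12 of 15 were lower (adjusted p = 0.00358), or adjusted p = 0.283 with an estimated correlation. Cd163l1 (SCART1), a scavenger receptor of gamma delta T cells, differed by -1.19 ± 0.38, and Trgv4, a gamma chain variable segment, by -0.81 ± 0.34. The list passed with array set as a block (adjusted p = 0.0381), with means of -0.28 in set A and -0.13 in set B, but in only 4 of 10 fits that left out 1 array. The blocked call was lost without WT 1 (adjusted p = 0.0798), WT 2 (0.0721), WT 3 (0.0970), he 1 (0.0582), me 1 (0.0623) or me 3 (0.192). With no block it was lost without WT 1 (0.0575) or me 3 (0.0706). The list also did not pass with the Gapdh ratio as a covariate, with or without the block.

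Receptors with inhibitory motifs, a class that recruits SHP-1, rose in me: 17 of 23 were higher (adjusted p = 0.000314), or adjusted p = 0.0528 with an estimated correlation. Cd5, a negative regulator of antigen receptor signals, differed by 0.35 ± 0.12, Cd22, a B cell receptor inhibitor, by 0.36 ± 0.22, and Klrb1b, a C-type lectin receptor, by 0.73 ± 0.46. Klrb1b was 0.22 without me 2 and 1.05 without me 3, Cd5 was 0.21 without me 3, and Cd22 was 0.55 without me 1. Array set as a block gave an adjusted p of 0.000129, with means of 0.18 in set A and 0.20 in set B, and it was the 1 list that fry called in the blocked fit (adjusted p = 0.0310). Without me 2 the list did not pass in the fit with no block (adjusted p = 0.112). Marker lists of B cells, myeloid cells and CD8 and NK cells were higher in the same arrays. Cd22 is also on the B cell list, and Klrb1b, on no marker list here, belongs to a family of natural killer cell receptors. Without the 5 members that a marker list holds, a setting chosen after seeing the data, the other 18 passed (adjusted p = 0.000343, or 0.000136 with the block). The marker lists do not name every receptor of other cells, Klrb1b for one, so this does not separate the receptor class from such cells. With the Gapdh ratio as a covariate the full list had an adjusted p of 0.0339, or 0.0573 with the block, and with the cre control 0.767, or 0.315 with the block.

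Glycolysis and hypoxia genes rose in me, with 19 of 24 higher (adjusted p = 5.19e-05), or adjusted p = 0.153 with an estimated correlation. Slc2a3, a glucose transporter, differed by 0.40 ± 0.14, Hif1a, the oxygen-regulated transcription factor, by 0.37 ± 0.21 (0.23 without me 1), and Ldha, lactate dehydrogenase A, by 0.15 ± 0.09; without normalisation between arrays Ldha changed sign. Array set as a block gave an adjusted p of 0.00167, with means of 0.07 in set A and 0.13 in set B. With the Gapdh ratio as a covariate the glycolysis and hypoxia list passed with the block and not without it. Interferon response genes also rose, 24 of 33 being higher (adjusted p = 9.66e-05), or adjusted p = 0.386 with an estimated correlation. Oas1a and Ifi27l2a, both interferon-induced, differed by 0.65 ± 0.30 and 0.61 ± 0.31, the second by 0.38 without me 3 and 1.00 without me 2. The list held with array set as a block (adjusted p = 0.00146), but its mean was 0.34 in set A and -0.0042 in set B. Without me 3 it did not pass (adjusted p = 0.0585, or 0.0874 with the block).

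The other lists that passed upward were lost with array set as a block. Genes of cell cycle G2/M were higher for 31 of 31 (adjusted p = 0.00156), or adjusted p = 0.650 with an estimated correlation, with Cenpa, the centromeric histone, at 0.35 ± 0.26 (0.19 without WT 3 and 0.55 without me 2). T cell antigen receptor signalling gave 0.00684, or adjusted p = 0.371 with an estimated correlation. For apoptosis the value was 0.00829, or adjusted p = 0.540 with an estimated correlation, with Birc2, an inhibitor of apoptosis, at 0.50 ± 0.11 and Casp4, an inflammatory caspase, at 0.58 ± 0.30. Glucocorticoid response gave 0.0183, or adjusted p = 0.168 with an estimated correlation, with Il1r2, the interleukin 1 decoy receptor, at 0.93 ± 0.25 and Fkbp5 at 0.36 ± 0.12 (0.23 without me 2). Effector Treg genes gave 0.0282, or adjusted p = 0.641 with an estimated correlation, with the chemokine receptors Cxcr3 at 0.60 ± 0.27 (0.35 without me 3) and Cxcr6 at -0.71 ± 0.24. Chemokine receptors and adhesion gave 0.0464, or adjusted p = 0.319 with an estimated correlation, with Ccr1 at 0.55 ± 0.18 and Itgb7, an integrin of gut homing, at 0.38 ± 0.14 (0.22 without me 3). With the block these 6 lists had adjusted p of 0.0992, 0.191, 0.189, 0.0767, 0.262 and 0.0920 in the order given. Leaving out 1 array also ended each of these calls in the fit with no block. Cell cycle G2/M was lost without WT 3 (adjusted p = 0.815, downward), me 1 (0.164) or me 3 (0.928). The T cell antigen receptor list was lost without WT 4 (0.139), me 2 (0.0534) or me 3 (0.0517), and apoptosis without WT 3 (0.111), WT 4 (0.0614) or me 1 (0.452). Glucocorticoid response was lost without WT 1 (0.0559), WT 4 (0.0525), me 1 (0.101) or me 2 (0.366), and effector Treg without WT 3 (0.882), WT 4 (0.0534), me 1 (0.960) or me 3 (0.148). Chemokine receptors and adhesion were lost without WT 2 (0.174), WT 3 (0.338), WT 4 (0.0611), he 3 (0.0746), me 1 (0.322) or me 2 (0.117). Platelet and megakaryocyte markers passed upward with the block (adjusted p = 0.0366) but not in the fit of all arrays with no block. The blocked call was lost without WT 1 (0.0588), WT 4 (0.0652), he 3 (0.0591), me 1 (0.0914) or me 3 (0.0706). With no block the platelet list passed when WT 3 was left out.

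**Figure D4:**
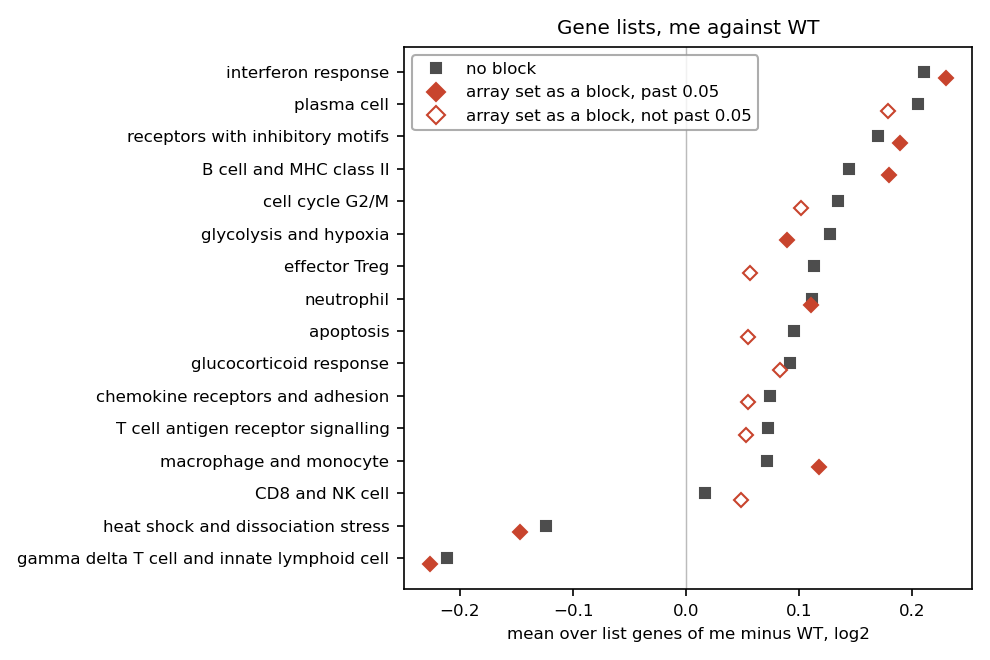
Mean me minus WT difference (log2) over the members of each of the 16 gene lists that passed with no block. Squares are means with no block and diamonds means with array set as a block, filled where the list also passed there; the interferon list has means of 0.21 and 0.23.

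Interferon response genes were higher in he than in WT, mostly through 1 of the 3 he arrays. Of 33 measured members 29 were higher in he (median 0.29, log2; adjusted p = 4.56e-14), or adjusted p = 0.868 with an estimated correlation. The list mean minus the WT mean of the same array set was 0.98 in he 2, 0.08 in he 1 and -0.03 in he 3. Ifit1, an interferon-induced inhibitor of viral translation, had a log2 value of 10.63 in he 2, 7.93 in he 1 and 7.47 in he 3, against 7.49 ± 0.08 (SD) in WT (n = 4). Usp18, which removes ISG15 from proteins, differed by 0.91 ± 0.52 (SE), Rtp4 by 1.01 ± 0.58 and Zbp1, a nucleic acid sensor, by 0.24 ± 0.10. Without he 2 these differences were 0.16, 0.18 and 0.15. The interferon list was the 1 list of 34 that passed in he, fry called 0, and with array set as a block it was again the 1 list called (adjusted p = 1.56e-11; means 0.08 in set A and 0.48 in set B). Without he 2 it did not pass (adjusted p = 0.479, or 0.532 with the block) and 7 other lists did; without he 3 the count was 12 and without WT 3 it was 5.

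**Figure D5:**
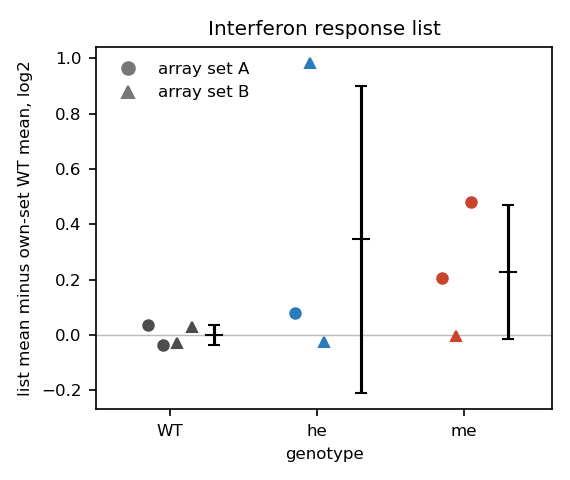
Mean log2 normalised intensity of the interferon response list minus the WT mean of the same array set, on each of the 10 arrays, by genotype. Points are single arrays, marked by array set, and bars are group means with SD; he 2 lies at 0.98 and me 3 at 0.48.

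Single genes differed less between he and WT. The named genes, taken by the smallest limma p in each direction, were higher by 0.32 ± 0.09 for Ankrd11, a chromatin regulator, 0.26 ± 0.08 for Ppp3ca, the calcineurin catalytic subunit, 0.26 ± 0.09 for Il6ra at a dim probe set, 0.22 ± 0.06 for Plekha2 and 0.20 ± 0.06 for Rps4l. Telo2 differed by -0.32 ± 0.09, Utp6, a ribosome assembly factor, by -0.27 ± 0.08, Prkci, an atypical protein kinase C, by -0.26 ± 0.08, Psmd12, a proteasome subunit, by -0.23 ± 0.06, and Wscd2 by -0.20 ± 0.06. Foxp3 differed by 0.14 ± 0.28, Il2ra by 0.11 ± 0.12, Ctla4 by 0.21 ± 0.35, Ikzf2 by 0.17 ± 0.11, Tnfrsf18 by -0.02 ± 0.07 and Cd4 by -0.03 ± 0.11. Foxp3, Il2ra, Ctla4, Ikzf2 and Plekha2 changed sign when each array was centred on its median. Leaving out WT 1 gave -0.0037 for Foxp3, WT 3 gave -0.06 for Ctla4, he 2 gave 0.01 for Tnfrsf18, and WT 2 and he 1 gave 0.03 and 0.04 for Cd4. Il2ra was 0.04 without he 3 and 0.19 without WT 3, and Ikzf2 was 0.26 without he 2. Jchain, chosen here after its values were seen, differed by 0.06 ± 0.43 (0.02 without he 1 and 0.11 without he 3). Limma called 0 probe sets with 134 at an unadjusted p under 0.05, and 0 with array set as a block with 961. Groups did not overlap at 1.04% of probe sets, where chance would give 5.71% in arrays free of sets.

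Between me and he, antibody transcripts and Bhlhe40 were again higher in me and Il17rb, Stab2 and Hes1 lower. Jchain differed by 2.17 ± 0.46 (log2, SE), Ighm by 1.46 ± 0.41, Bhlhe40 by 0.70 ± 0.13, Hmgn3 by 0.63 ± 0.14, Ttn by 0.46 ± 0.09 and Csnk2a1, a casein kinase 2 subunit, by 0.41 ± 0.09. Il17rb differed by -0.89 ± 0.19, Stab2 by -0.76 ± 0.17, Hes1 by -0.41 ± 0.08 and Hnrnpf, an RNA-binding protein, by -0.28 ± 0.07. Among Treg genes Il2ra differed by -0.33 ± 0.13, Ctla4 by 0.47 ± 0.37, Foxp3 by -0.04 ± 0.30, Ikzf2 by 0.0050 ± 0.12, Tnfrsf18 by 0.03 ± 0.08 and Cd4 by 0.16 ± 0.12. Ctla4 was 0.16 without me 1 and 0.65 without me 2, and Cd4 was 0.09 without he 1 and 0.25 without he 3. Cd83 and Penk, both on the Treg signature list, differed by 0.54 ± 0.18 and 0.75 ± 0.27. Foxp3 and Ikzf2 changed sign with array set as a block (0.18 and -0.02), Foxp3 also without he 2, he 3 or me 1 (0.04, 0.10 and 0.19), Ikzf2 without he 2 (-0.08) or me 1 (-0.07), and Tnfrsf18 without he 2 (-0.0051) or me 1 (-0.03). Jchain differed by 2.78 in set A and 0.86 in set B, and Il17rb by -1.10 and -0.79. Limma called 0 probe sets, with 301 at an unadjusted p under 0.05, and 0 with array set as a block with 1447. Without me 2 the count was 2. Groups did not overlap at 1225 probe sets (2.72%, where chance would give 10% in arrays free of sets).

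Of 34 lists, 9 passed between me and he, 6 upward and 3 downward, 0 with an estimated correlation and 0 with fry. Neutrophil markers rose (18 of 21 higher, adjusted p = 0.00125), or adjusted p = 0.392 with an estimated correlation, with S100a8 at 0.54 ± 0.14. Plasma cell markers rose (13 of 16 higher, adjusted p = 0.00155), or adjusted p = 0.392 with an estimated correlation. Glycolysis and hypoxia genes rose (20 of 24, adjusted p = 0.00155), or adjusted p = 0.455 with an estimated correlation, with Slc2a3 at 0.42 ± 0.15. Genes of cell cycle G2/M (28 of 31 higher, 0.00306), apoptosis (21 of 26, 0.00953) and oxidative phosphorylation (28 of 36, 0.0171) rose, or adjusted p = 0.783, 0.652 and 0.605 with an estimated correlation. Casp4, on the apoptosis list, differed by 0.72 ± 0.32. Interferon response genes passed downward (23 of 33 lower, adjusted p = 0.00953), or adjusted p = 0.762 with an estimated correlation, with means of 0.26 in set A and -0.48 in set B and Igtp, an interferon-induced GTPase, at -0.41 ± 0.30. That direction rested on he 2: without it the list passed upward (adjusted p = 0.000124) and Igtp differed by -0.0090. It did not pass without me 2 (0.553) or with array set as a block (0.103). Heat shock genes fell (16 of 26 lower, adjusted p = 0.00953), or adjusted p = 0.455 with an estimated correlation, with Hspa1a at -0.32 ± 0.11. Gamma delta T cell and innate lymphoid cell markers fell (10 of 15 lower, adjusted p = 0.0137), or adjusted p = 0.492 with an estimated correlation. In the blocked fit 6 lists passed, and the heat shock, neutrophil and gamma delta lists were the 3 shared with the fit without it. The array quality measures changed these calls too. With the Gapdh ratio as a covariate 9 lists passed, of which the heat shock and neutrophil lists were 2 of the 9 above. The means of cell cycle G2/M, apoptosis and oxidative phosphorylation turned from 0.15, 0.14 and 0.07 to -0.04, -0.0057 and -0.02, and none of the 3 passed (adjusted p = 0.254, 0.724 and 0.647). With the cre control 1 list passed, apoptosis, and with the block and the cre control 6 passed, among them cell cycle G2/M downward (mean -0.26, adjusted p = 0.00570). Without he 1 the count with no block was 4 and without he 3 it was 14.

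Most of the me and he calls were lost when 1 array was left out. With no block the neutrophil list was lost without he 1 (adjusted p = 0.0832) or me 2 (0.0846), plasma cell markers without he 1 (0.0991) and apoptosis without he 3 (0.954) or me 1 (0.213). Cell cycle G2/M was lost without he 2 (0.586, downward) or me 3 (0.452), and oxidative phosphorylation without he 1 (0.0511), he 2 (0.296), me 1 (0.155) or me 3 (0.120). Heat shock was lost without he 1 (0.558) or me 2 (0.499), and the gamma delta list without he 1 (0.408), he 2 (0.402), me 2 (0.106) or me 3 (0.0821). In the blocked fit the heat shock, inhibitory receptor, macrophage and B cell lists were lost without he 1 (0.0812 for each) and the neutrophil list without me 2 (0.0792). The blocked gamma delta call was lost without he 1 (0.147), he 2 (0.455) or me 3 (0.154).

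Over the 3 genotypes together limma's F test called 0 probe sets, with 199 at an unadjusted p under 0.05, and 0 with array set as a block with 1287. Without me 2 the unblocked count was 2.

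The me minus WT and he minus WT differences share the WT arrays. Their covariance across 18193 genes, which are not independent replicates, was 6.99e-05 (Pearson r = 0.0046). Leaving out 1 array moved it from -0.0164 (without me 2) to 0.0185 (without WT 3), so its size and sign rest on single arrays. In 100 simulated pairs of unchanged groups against the same number of WT arrays the mean was 0.03, and 67 were at least as high. The blocked covariance was 0.00428 (r = 0.402), and 51 of 100 simulations were at least as high. With the WT arrays split between both comparisons the covariance ran from -0.12 to -0.0014 without the block and from -0.0017 to 0.0022 with it. The -0.12 came with me against WT 3 and WT 4, both of set B, and he against WT 1 and WT 2, both of set A. That split brings the shift between sets into the me and he differences with opposite signs. The simulations without the block drew arrays without keeping the balance of sets.

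Genes that lie beside Ptpn6 were also compared, since mice that carry a mutant allele can carry linked alleles. Of the 100 annotated genes on either side in the GRCm38.p6 gene table, 79 were measured. Limma called 0 of them in each comparison, and 0 genes elsewhere, so Fisher's exact test could not be run on called genes. At an unadjusted p under 0.05, a threshold chosen after seeing the data, 5 of the 79 differed between me and WT, 0 between he and WT and 1 between me and he. The blocked counts were 11, 2 and 2. Slc2a3, named above, lies among these neighbours.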

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

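The tests of genotype and sex for the array sets, all 3 tests for Jchain and Ighm, and the tests of linked alleles and natural killer receptor cells for genes near Ptpn6 were chosen only after the result was seen, as were the fits with array set as a block and the unadjusted threshold for genes near Ptpn6.

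Among 113 results tested within the 4 WT arrays (79 genes and 34 list means), 4 had 1 array far from the other 3 (3.54%), where chance gives about 1 in 20. Hmgn3 was 9.64 (log2) in WT 4 and 9.12 on average in the others. Slc2a3 was 10.89 in WT 1 and 10.49 in the others. Psmd12 was 10.50 in WT 1 and 10.58 in the others. The mean of the gamma delta T cell and innate lymphoid cell list was 8.69 in WT 4 and 8.97 in the others.

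The arrays form 2 sets, and neither genotype nor sex accounts for the sets: all 3 genotypes and both of the 2 sexes have arrays in each set. If the sets differed in the RNA of the cells, probe sets of 1 gene should shift together. Across 9010 genes, which are not independent, the shifts of the 2 brightest probe sets had r = 0.210, and r = 0.217 among 4608 genes with both probe sets at or above the median level. A candidate explanation is a difference in amplification or hybridisation between the sets, a test whose outcome was not known when it was chosen. The cre hybridisation control was 10770 to 16150 in set B and 21736 to 27388 in set A apart from me 3, which had 13192. No r was measured for a known difference in RNA, so the low r does not exclude one. The labels give no batch or date, so a difference in amplification or hybridisation stays a hypothesis.

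Jchain and Ighm were higher in me. Within the array sets 4 of 4 differences were above 0. The me and WT arrays do not overlap for either gene, so this outcome was fixed and does not test array set. With array set as a block the differences were 2.13 ± 0.36 (log2, SE) for Jchain and 1.48 ± 0.26 for Ighm. Light chain probe sets had a median blocked shift of 0.33 (9 of 9 higher, 0.00095 to 1.87). Without the block 6 of 9 were higher (median 0.19), and within sets A and B 9 and 5 were. Of the light chain probe sets the 3 brightest, each listing several kappa light chain gene segments, shifted by 1.87, 1.46 and 1.21. B cell list genes other than Ighm had a median of 0.21 (14 of 17 higher, -0.59 to 0.52), against 10 of 17 higher without the block (median 0.03) and 14 and 13 within sets A and B. Antibody-producing cells and B cells that passed the CD4+CD25+ isolation may both contribute in me; they cannot be told apart, because both medians lie between the bounds set for each, and a change inside the Treg cells was not tested.

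More genes near Ptpn6 than elsewhere had an unadjusted p under 0.05 between me and WT with array set as a block: 11 of 79 near genes against 916 of all 18144 (Fisher's exact p = 0.00199). Phc1 (0.39 ± 0.14, log2 difference without the block, SE), Cdca3 (0.64 ± 0.23), Cops7a (-0.22 ± 0.06) and Pianp (-0.99 ± 0.43), chosen after their values were seen, are among them. The excess did not rest on the natural killer receptor genes of the region. It remained without the Klr, Clec and marker genes (10 of 71 against 865 of 17814, Fisher's exact p = 0.00229). Of the 11 genes only Klrg1 was left out in this way, so other transcripts of cells that use these receptors were not tested. The other blocked comparisons showed no excess: 2 of 79 between he and WT (2.53% against 2.29% of all genes, Fisher's exact p = 0.703) and 2 of 79 between me and he (2.53% against 3.53%, p = 1). Alleles linked to the mutation would also part me from he, so these counts do not favour them, but differences that are smaller between he and me would also give few. Such alleles may still contribute. The he minus WT over me minus WT difference had a median ratio of 0.35, against 0.34 in 905 other genes (permutation p = 0.948). Both differences share the WT arrays, and the genes were picked by their me minus WT p. A ratio above 0 can thus arise without a change in he, as simulated unchanged groups had a mean blocked correlation of 0.37. Linked alleles, an effect of Ptpn6 loss and the spread of the shared WT arrays therefore cannot be told apart. Of 35 splits 1 reached 11, the real one, and the highest other gave 9, but only 18 of them keep the real balance of array sets, which allow no share under 0.05, and the block was chosen after the values were seen.

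Other splits of the same arrays into groups of the same sizes were fitted for the counts. The real probe set count was 0 for me and WT, for he and WT and in the F test, so all 35, 35 and 100 splits were as large by construction, which says nothing about chance. The highest other for me and WT gave 18346, with WT 3, WT 4 and me 2 against the rest, a split that follows the array sets and points to that structure. The highest other for he and WT gave 23571 with WT 1, WT 2 and he 1, again the sets, and in the F test it was 20287. With 10 splits of me and he no share under 0.05 can be had; the real count and the highest other (10 of 10 as large) were both 0. In the blocked fit the real me and WT count of 3 was reached by 2 of 35 splits, the highest other giving 7, so chance is not excluded. For gene lists between me and WT the real 16 was reached by 1 of 35 splits, the highest other giving 14, but the 18 splits with the real balance of array sets (median 5.5) allow no share under 0.05, and array quality measures that follow me are not excluded. With the block the real 9 was reached by 7 of 35, the highest other giving 16, and chance is not excluded. For he and WT lists the real 1 was reached by 34 of 35, the highest other giving 15. For me and he lists 10 splits allow no share under 0.05; the real value was 9, reached by 4, and the highest other was 16.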

How the results depend on the processing

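The settings with array set, the first principal component, sex, the Gapdh ratio, the cre control, marker list members or an unadjusted p were chosen after seeing the data; the others were planned. The cause was not tested for the changes below unless stated. The number of arrays limits the precision.

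For the probe set counts, the main values were 0 in every comparison. Array weights gave 2 between me and WT, 27308 between me and he and 22802 in the F test; the weights were 26.6 for me 3 and 7.10 for he 2 and 0.27 to 0.83 for the others. The weights did not converge and rest on those arrays, so calls with them are not read as support. For me against WT the count was 3 with array set as a block, 3 with array set as a block, trend and robust prior, 5 with the first component as a covariate, 6 with array set as a block and a filter on low values and 5 with array set as a block and without he 2, and the F test gave 2 with the block and the filter. The me against WT count stayed 0 with me 3 counted in set B in the block, and with array set and sex as blocks. Leaving out 1 array in turn gave 0 to 2 for me against WT, 0 to 2 for me against he and 0 to 2 in the F test, and 0 throughout for he against WT. The replicate block, which treats equal replicate numbers as paired, gave 0 probe sets and 13, 1 and 9 lists; 3 of 10 arrays correlated best with an array of their own number. Deviations from the group means correlated over 0.1 in 5 of 9 same-numbered pairs, which are the 5 within an array set. After array set 6 of 9 did, with all 3 of replicate 1 (0.20, 0.15 and 0.25) and he 3 with me 3 (0.32) among them, while WT 2 with he 2 (-0.16) and WT 3 with he 3 (-0.19) did not. Not every pair did in either form, so the numbers were not treated as pairs, and a link among some of them stays open.

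Ptpn6 kept its sign in every one of 30 settings at both probe sets, from -1.30 to -0.88 (adjusted p 0.0245 to 1) at the dimmer and -0.80 to -0.62 (0.0371 to 1) at the brighter for me against WT. Its groups do not overlap, so in the settings that left out 1 array with no block the sign could not change. It passed at the brighter for me against WT with the first component (-0.70), the block and filter (-0.69) and the block without he 2 (-0.68), and at the dimmer with array weights (-1.08), the first component (-1.07), the block and filter (-1.06) and the block with trend and robust prior (-1.06). Array weights, which did not converge, also gave calls for me against he (-0.30 and -0.56).

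Named genes kept their sign and side in 1122 of 1135 values for me against WT, 485 of 500 for he against WT and 502 of 539 for me against he. Those that changed sign, with the altered values, were Tnfrsf18 in me against WT (-0.012 with the replicate block, -0.018 with no normalisation, -0.0055 with array set as a block), Ldha (-0.016 with no normalisation), and Plekha2 in he (-0.0081 with centring). With no normalisation and with centring, he minus WT was -0.040 and -0.060 for Foxp3, -0.061 and -0.081 for Il2ra, -0.020 and -0.040 for Ctla4 and -0.070 and -0.090 for Ikzf2, and Ctla4 was -0.16 with array weights. For me minus he Foxp3 was 0.11, 0.15 and 0.18 with no normalisation, centring and array set as a block, Ikzf2 was -0.024 with the block and Socs2 0.18 with array weights. Leaving out single arrays gave, for me minus WT, -0.12 to 0.33 for Foxp3, -0.055 to 0.066 for Tnfrsf18 and 1.82 to 2.91 for Jchain; for he minus WT, -0.0037 to 0.36 for Foxp3, -0.057 to 0.41 for Ctla4, -0.045 to 0.013 for Tnfrsf18 and -0.12 to 0.042 for Cd4; and for me minus he, -0.26 to 0.19 for Foxp3, -0.083 to 0.068 for Ikzf2, -0.033 to 0.088 for Tnfrsf18 and 1.76 to 2.85 for Jchain.

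Gene lists changed more. With an estimated correlation, with fry and no block, and with the block plus an estimated correlation, 0 passed in each comparison. With the filter on low values 12 passed for me against WT, without the effector Treg, neutrophil, macrophage and CD8 and NK cell lists. With the mean of all probe sets of each gene 18 passed, the Treg signature and ribosomal protein lists among them. The block alone let 9 pass for me against WT, with set and sex 10, and with the block without he 2 9. For he against WT 6 passed with no normalisation, 2 with set and sex and 3 with the block without he 2, and 5 passed for me against he with set and sex. With the block and fry 1, 0 and 0 passed. With the block and members shared with a marker list left out 10 passed for me against WT. The Gapdh ratio gave 9, the block and the ratio 9, the cre control 3 and the block and the cre control 5 for me against WT. For he against WT the cre control gave 2 with and without the block, and for me against he it gave 1 without. Leaving out single arrays gave 10 to 16, 1 to 12 and 4 to 14 lists. The covariance was -0.12 with WT 3 and WT 4 set against me, the split that follows the array sets. Near Ptpn6 the unadjusted threshold gave 5, and 11 with the block, for me against WT, 2 with the block for he, and 1, or 2 with the block, for me against he. The F test has no form on 2 groups alone and was not run there.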

Other observations

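The cytokine genes Il4 and Il13, products of type 2 helper T cells, and Il17rb were the 3 members of the helper T cell list that passed with array set as a block, a fit chosen after seeing the data, when adjusted over the list alone. Their blocked me minus WT differences were -0.25 ± 0.05 (log2, SE), -0.27 ± 0.06 and -1.17 ± 0.15, and all 3 me arrays were lower than the WT mean of their own set for each gene. Within sets A and B they were -0.29 and -0.16 for Il4 and -0.22 and -0.31 for Il13. None passed over all genes, and the list did not pass (adjusted p = 0.064 with the block). Il6ra, the interleukin 6 receptor chain of resting T cells, differed by -0.79 ± 0.17 with the block at its brighter probe set and passed adjusted over its list alone, where 2 of 22 members did.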
